A study of Rattus norvegicus with 2 samples.

How the data were processed

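Poly(A) RNA of cultured neonatal rat ventricular cells was measured by RNA-seq in 2 libraries, 1 per group. Per the labels' protocols, ventricular cells taken at postnatal day 0 were dissociated with trypsin and left on uncoated plastic for 2 h, and the cells that did not attach were plated as cardiomyocytes, with a stated purity above 90%. Cultures were treated for 7 days with adeno-associated virus (AAV, serotype 2/9) carrying short hairpin inhibitors of miR-99/100 and let-7, here the anti-miR library, or served as control. The labels describe the control in different ways: the treatment tag names an empty virus, and the protocol a mock transduction. Libraries were made with a strand-specific Illumina TruSeq kit, per the labels' protocols.

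The deposited values are a scaled read signal per gene. Per the file headers, HOMER's analyzeRepeats counted reads over exons of RefSeq transcripts of the rat build rn4, on the strand opposite to the read, with no adjustment of totals and 1 transcript kept per gene. STAR 2.2.0c, CASAVA 1.8.2 and HOMER are named without a role per the submitters' processing notes; how reads with several matches were handled is not given in the sources used here. The deposited signal sums to 15423813 in the control and 15423812 in the anti-miR column although the header asks for unadjusted totals, so a scaling step followed the counting; which one is not given in the sources used here. The table holds 16847 rows and 16846 gene symbols; 1 symbol has more than 1 row, at 0 throughout, and the row with the highest mean was kept. Symbols and rn4 coordinates are those of the deposited table. Of its accessions, 15849 matched the rat RefSeq gene table used here, 13273 of them under the same symbol, and no coordinates were taken from that table.

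Whole reads were recovered from the signal. Low values in a column are whole multiples of the value of 1 read, 0.962 in the control and 1.04 in the anti-miR column. Of the values up to 400 reads, 100% in each column were whole within 0.005 deposited units. Depth was 16031780 reads on genes in the control and 14815846 in the anti-miR library, and 3 reads, the limit that a count of 0 allows, correspond to 0.187 and 0.203 reads per 1000000 (RPM). Levels are given as RPM, the deposited signal per 1000000 of its column total, with no correction for transcript length. Ratios are log2((anti-miR + 0.1)/(control + 0.1)) of RPM values, a scale that understates the difference of low genes. Each ratio of reads carries an exact Clopper-Pearson 95% interval. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

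With 1 library per group no spread within a group can be estimated, so no p-value across genes is given and every comparison describes these libraries. Genes with a mean of at least 1 RPM were kept, 10365 in all, and a ratio of at least 2 was the rule for a gene being higher or lower. Each gene was also set against the central 95% of the log2 ratios of the 500 genes nearest to it in level. For each gene list with 5 or more members above the floor, the median log2 ratio, its 95% order-statistic interval over members and the members at least 1.5-fold higher or lower were computed. The median's percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called apart when its percentile lay outside 2.5 to 97.5. An exact binomial test on the recovered reads, Benjamini-Hochberg adjusted at 0.05, was added after the data were seen; it compares the 2 libraries, not the conditions. A second list of 65 mitotic genes, sharing none with the first, was chosen after the first list's median was seen and before its own was computed. Of these, 47 lay above the floor. Genes on any other list and genes of the 12 highest and 12 lowest ratios described below could not enter it, Dlgap5 among them.

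The samples' groups, the rules for ratios, lists and named genes and most alternatives were fixed before the data were examined. The lists covered commonly cited let-7 and miR-99/100 targets. Heart lists were sarcomere, calcium and ion channel, fetal or stress, and cardiac transcription factor genes. Further lists covered G1/S and G2/M genes, cell-cycle inhibitors, oxidative phosphorylation, fatty acid oxidation, glycolysis, the mevalonate pathway, chromatin remodelling, ribosomal proteins and YAP, interferon, NF-kB, unfolded protein response, immediate early, hypoxia and lysosome genes. Marker lists covered fibroblasts, smooth muscle, endothelium, leukocytes, epicardium, erythroid cells and glia or neurons. A few genes stand on more than 1 list, among them Plk1 (miR-99/100 targets and G2/M) and Slc2a1 and Pdk1 (glycolysis and hypoxia).

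Genes are named by rule: the 12 highest and the 12 lowest ratios among genes of at least 5 RPM, leaving out symbols that start with LOC, RGD, Mir, Snor or Rn (0 would have entered); in each list the highest and lowest ratio and the 2 highest levels; and a fixed set of targets and heart genes with the hairpin genes of the targeted miRNAs. Other named genes were chosen after their values were seen and are marked as such. Not every gene that the rules select is reported here.

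Alternatives were the pseudocount (1 and 0.01 RPM), the expression floor (none, and 10 RPM), the scaling (median ratio or trimmed mean of ratios set to 0), summing rows of a symbol, and ratios of 1.5 and 3. The exact binomial test and a floor of 5 RPM were added after the data were seen. An analysis of seed sites in 3′ UTRs was fixed beforehand and not run, because 3′ UTR sequences were not used here.

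The scripts were tested on simulated data for this comparison, with all 16847 rows and 15 reads per simulated molecule. The ratio rule found 55% of 100 genes with a true 2-fold difference, which equals its cut-off, and 100% of 100 genes with a true 4-fold difference, and of 10148 unchanged genes it called 491 higher and 547 lower. A list of 30 genes raised 1.5-fold reached percentile 100, and 4% of 200 unchanged lists fell outside the central 95%. A dispersion index was defined as the median squared difference between the libraries in a class of genes over its median for independent reads; the simulation recovered 18.1 with 15 copied reads and 1.04 with independent reads. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.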

Results

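Gene expression was measured by strand-specific poly(A) RNA-seq in cultures prepared as neonatal rat ventricular cardiomyocytes. There was 1 control library and 1 library from cultures transduced for 7 days with AAV carrying short hairpin inhibitors of miR-99/100 and let-7, so no difference has a replicate check. The control library held 16031780 reads on genes and the anti-miR library 14815846, with 10908 and 11367 genes above 0. The control is an empty virus by one label and a mock transduction by another. Levels are RPM, reads on a gene per 1000000 reads on all genes, given for the control first, and positions are on build rn4.

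The comparison asks how knockdown of the miR-99/100 and let-7 families alters the transcriptome of these cells. A list of 30 mitotic genes was higher in the anti-miR library, with a median 1.55-fold above the control, while another list of 47 mitotic genes lay inside the range of random lists. Ribosomal protein genes were higher by a median of 1.20-fold, and immediate early genes were lower, with a median ratio of 0.763. NF-kB target genes had a median ratio of 0.783, but the interval over members included no difference, and with a floor of 10 RPM the list lay inside the range of random lists. Commonly cited targets of let-7 and of miR-99/100 differed little as groups, with median log2 ratios of −0.03 and 0.10. In both libraries extracellular matrix and macrophage transcripts were abundant and most sarcomere transcripts scarce.

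The knockdown itself could not be read from these libraries, since poly(A) counts do not measure mature miRNAs. Of 13 hairpin genes of let-7, miR-99 and miR-100, 8 had 0 reads in both libraries, among them Mir100 and Mir99a. Mirlet7a-2 (chromosome 8, 44525769 to 44525864) had 13 and 5 reads, a ratio of 0.416 with a counting interval of 0.116 to 1.24, and Mirlet7b had 10 and 2 reads, a ratio of 0.216 with an interval of 0.0231 to 1.02. Both intervals include 1, so a difference was not detectable at this depth.

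Fibroblast and matrix genes led the transcriptome of both cultures. Col1a1 (chromosome 10, 83622438 to 83639368), encoding a chain of type I collagen, had 49138 RPM in the control and 50088 in the anti-miR library. Col3a1, of type III collagen, had 26226 and 26168. The 24 fibroblast markers together made up 15.98% and 16.10% of reads. Their median log2 ratio was 0.05 (95% interval over members −0.00 to 0.16), at percentile 84.6 of matched random lists, and 0 members were 1.5-fold apart; Dcn, of decorin, was highest at 0.56 and Ddr2 lowest at −0.19. Markers of macrophages and other leukocytes had median levels of 306 and 328 RPM over 20 measured genes. The lysozyme gene Lyz2 had 2937 and 3937 RPM, although its reads are also listed under Lyc2, annotated at the same place. The median of the 17 leukocyte markers above the floor was −0.01 (−0.15 to 0.15, percentile 41.1), with C1qa, a complement subunit, at −0.57 and Cd68 at −0.30.

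Most cardiomyocyte transcripts were low by comparison. The 23 measured sarcomere and Z-disc genes had median levels of 1.19 and 2.23 RPM. The highest were Tpm1 (441 and 461 RPM), a tropomyosin that other muscle cells and fibroblasts also express, and Cryab (258 and 241), a small heat shock protein. Tnnt2, the cardiac troponin T gene, had 147 and 161 RPM and Actc1, of cardiac alpha actin, 76.97 and 88.76; both were chosen after their values were seen. Myh6, the alpha cardiac myosin heavy chain, lay below the floor with a mean of 0.776 RPM, where genes of the list went both ways. It had 0 reads in the control and 23 in the anti-miR library, with a counting interval of the ratio from 6.22 upward. Its neighbour and paralog Myh7 had 6.18 and 11.5 RPM, a ratio of 1.87 (counting interval 1.45 to 2.42) and a log2 ratio of 0.89, inside its like-level range of −1.32 to 1.27, and reads shared by the pair cannot be told apart. Of the 14 sarcomere genes above the floor, 4 were at least 1.5-fold higher and 2 lower, with a median of 0.25 (−0.10 to 0.98) at percentile 94.0. Ldb3, a Z-disc protein, had 0 and 43 reads, with a counting interval of the ratio from 12.1 upward, and Myl2, the ventricular regulatory light chain, had 30 and 5 reads. Both lay inside their like-level ranges, −4.51 to 5.11 and −4.51 to 5.06 on the log2 scale. The 13 calcium and ion channel genes above the floor had a median of 0.10 (0.02 to 0.69, percentile 76.5), with 3 at least 1.5-fold higher and 0 lower. Casq2, the calsequestrin of the heart, was highest at 1.11, Kcnj2 lowest at −0.33, and the pump gene Atp2a2 stood at 354 and 396 RPM.

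**Figure D1:**
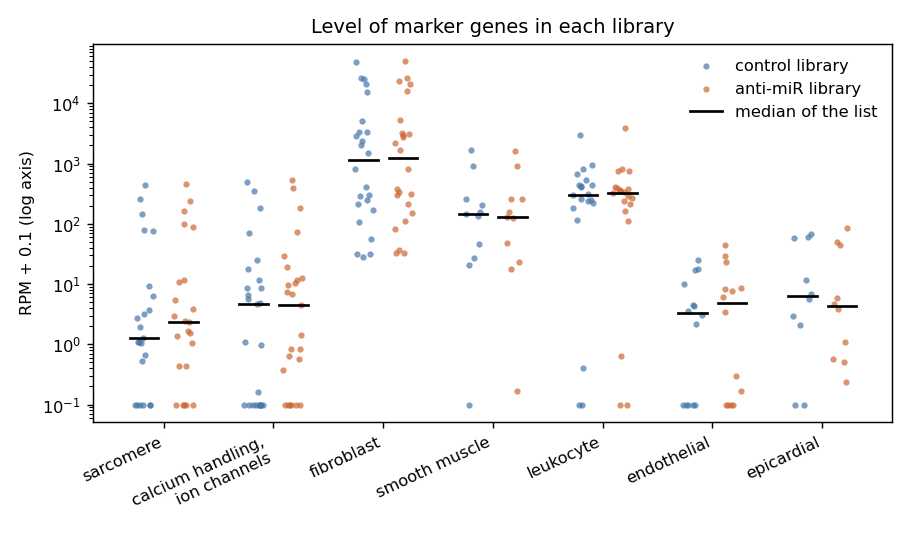
Levels of the genes of 7 lists in the control and the anti-miR library, in RPM plus 0.1 on a log axis, with 1 point per gene and a bar at the list median. Fibroblast markers have medians of 1162 and 1250 RPM and leukocyte markers 306 and 328, against 1.19 and 2.23 for sarcomere genes.

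Fetal and stress genes of the heart differed in both directions. Nppa, encoding atrial natriuretic peptide, had 5.68 and 9.38 RPM, and Nppb had 0 and 3 reads. Rcan1, a calcineurin regulator, was lower at −0.68. The list's median was 0.02 (−0.68 to 0.89, percentile 54.1) over 8 genes, 2 of them at least 1.5-fold higher and 1 lower. Among 12 cardiac transcription factors and progenitor markers, with a median of 0.11 (−0.40 to 0.33, percentile 77.8), Gata4 had 80.5 and 98.6 RPM. Tbx20 was highest at 1.04 and Myocd, the myocardin gene, lowest at −0.76.

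Markers of other heart cells were mixed. Smooth muscle markers had a median of −0.02 (−0.24 to 0.11, percentile 36.4) over 10 genes, 0 of them 1.5-fold apart, with Tagln at 901 and 909 RPM. The 10 endothelial markers above the floor had a median of 0.59 (−3.33 to 1.12) at percentile 97.8, with 5 at least 1.5-fold higher and 2 lower. Flt1, a VEGF receptor, had 24.7 and 44.9 RPM. Pecam1 had 0 and 50 reads, with a counting interval of the ratio from 14.1 upward. Plvap had 33 and 0 reads, with an interval from 0 to 0.128. The log2 ratios of Pecam1 and Plvap, 5.12 and −4.43, lay inside the like-level ranges of −4.03 to 5.23 and −4.51 to 5.06. All 14 measured endothelial markers together came to 86.3 and 131 RPM. Epicardial markers had a median of −0.34 (−1.87 to 0.34, percentile 5.38) over 8 genes, 3 of them at least 1.5-fold lower, with the keratin gene Krt19 at −1.87, inside its like-level range of −4.51 to 5.06, and Aldh1a2 at 0.34. Erythroid and glial or neuronal lists had 2 and 4 genes above the floor, too few for a median, with sums of 38.9 and 43.3 and of 28.5 and 37.5 RPM.

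Cited targets of the inhibited miRNAs lay close to 0 as groups. Over 31 let-7 targets above the floor the median log2 ratio was −0.03 (−0.34 to 0.11) at percentile 21.8, with 2 genes at least 1.5-fold higher and 2 lower. The let-7 targets Hmga2 and Lin28a had 0 reads in both libraries. Igf2bp1, an oncofetal mRNA-binding protein, had 49 and 7 reads, a log2 ratio of −2.46, within the range of −3.69 to 5.23 that covered the central 95% of genes of like level. Igf2bp2 had 24.6 and 24.2 RPM, and the cyclin gene Ccnd1 had 275 and 298. Ccnd2 was lower at −0.47 and Cdc34 stood at −0.12, while Arid3b was highest in the list at 0.78. Col1a2 and Tgfbr1, the most abundant members, had log2 ratios of 0.02 and −0.39.

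The 24 targets of miR-99/100 above the floor had a median of 0.10 (−0.23 to 0.36) at percentile 76.4, with 2 genes at least 1.5-fold higher and 0 lower. Fntb (chromosome 6, 99427967 to 99511373), the beta subunit of farnesyltransferase, was the lowest member. It had 35.1 and 23.5 RPM, a ratio of 0.669 (counting interval 0.584 to 0.766) and a log2 ratio of −0.58, inside the like-level range of −0.66 to 0.71. Smarca5 (chromosome 19, 29122301 to 29155293), the ISWI chromatin remodelling ATPase, had 51.2 and 59.9 RPM, a ratio of 1.17 (1.06 to 1.29) and a log2 ratio of 0.23, inside its range of −0.56 to 0.57. Mtor had 76.1 and 74.7 RPM and Igf1r, also a cited let-7 target, 26.1 and 19.4. Plk1, a mitotic kinase, was highest at 0.75, and the kinase gene Akt1 and the flippase subunit gene Tmem30a, the most abundant, stood at 0.28 and −0.10. The 14 chromatin remodelling genes, which include Smarca5, had a median of 0.10 (−0.08 to 0.28, percentile 85.0), with Smarca1 at 0.66 and Baz2a at −0.26. The mevalonate and prenylation list had a median of 0.05 (−0.10 to 0.34, percentile 65.1) over 22 genes, with Lss at 0.63 and Mvd at −0.65.

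Genes of G2/M and mitosis on the list fixed beforehand were higher in the anti-miR library as a group. Of 30 above the floor, 17 were at least 1.5-fold higher, 1 was at least 1.5-fold lower and 12 lay between, and their summed level was 469 and 655 RPM. The median log2 ratio was 0.63 (0.39 to 0.73), and 0 of 10000 matched random lists had a median as high. Racgap1 (chromosome 7, 138366356 to 138395716), a component of the centralspindlin complex of cytokinesis, had 7.17 and 23.0 RPM, a ratio of 3.21 (2.59 to 4.0), above its like-level range of −0.80 to 0.99 on the log2 scale. Top2a, topoisomerase II alpha, had 45.1 and 70.1 RPM at 0.63, above its range of −0.54 to 0.56. The proliferation marker Mki67 had 57.6 and 63.2 RPM at 0.13, and the checkpoint kinase gene Bub1 was lowest at −0.59. Cdk1 at 1.15 and the cyclin gene Ccnb1 at 1.13 were chosen after their values were seen. A further 47 mitotic genes above the floor, none on this list and chosen after its median was seen, had a median of 0.19 (−0.07 to 0.56) at percentile 90.9, with 15 at least 1.5-fold higher and 5 lower. Genes of the 12 highest and 12 lowest ratios, such as Dlgap5, could not be among these 47.

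G1/S and DNA replication genes had a median of 0.25 (0.10 to 0.74) at percentile 94.5, inside the range of random lists, with 9 of 28 at least 1.5-fold higher and 3 lower. The replication licensing gene Cdc6 had 0 and 85 reads, with a counting interval of the ratio from 24.4 upward. Its log2 ratio of 5.87 lay above its like-level range of −2.29 to 2.64. Mcm10 was lowest at −1.08, and Pcna had 80.3 and 92.7 RPM. The 19 cell-cycle inhibitors and p53-induced genes had a median of −0.01 (−0.25 to 0.05, percentile 33.8), with 1 gene at least 1.5-fold higher and 1 lower. Btg2, an antiproliferative gene, was lowest, with 108 and 54.5 RPM and a log2 ratio of −0.98, below its like-level range of −0.45 to 0.47. Cdkn1a, encoding p21, had 301 and 221 RPM at −0.45, below its range of −0.32 to 0.36.

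Ribosomal protein genes were mostly higher, by small amounts. Of 34 above the floor, 31 were higher, and the median was 0.27 (0.19 to 0.29), with 0 of 10000 random lists as high and 1 gene at least 1.5-fold higher. Rplp0 and Rpl3, the most abundant, had log2 ratios of 0.26 and 0.29, Rpl6 was highest at 1.20 and Rpl10a lowest at −0.37. Reads of these genes are uncertain where near-identical pseudogenes exist, and Rpl38 had 0 reads in both libraries. Glycolysis genes had a median of 0.22 (−0.17 to 0.48) at percentile 99.8 over 18 genes, 2 of them at least 1.5-fold higher and 0 lower. The aldolase gene Aldoa had 672 and 828 RPM, Aldoc was highest at 1.02 and Pfkfb3 lowest at −0.39, and Gapdh had only 45 and 34 reads. Gapdh and Rpl38 were chosen after their values were seen. Hypoxia-induced genes had a median of 0.23 (0.00 to 0.58) at percentile 99.1, with 3 of 15 at least 1.5-fold higher and 0 lower. Ankrd37 had 3 and 50 reads, a ratio of 18.03 (5.83 to 90.4) and a log2 ratio of 3.60, inside its like-level range of −3.69 to 5.23, while Vegfa had 165 and 169 RPM. With a floor of 10 RPM the hypoxia list lay at percentile 95.8, inside the range of random lists.

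Other metabolic lists were not apart from random lists. Oxidative phosphorylation genes had a median of 0.08 (−0.01 to 0.20, percentile 90.8) over 36 genes, with 1 at least 1.5-fold higher, Cox6a2, and 1 lower, Cycs. Atp5b had 844 and 969 RPM. Genes of fatty acid uptake and oxidation had a median of 0.07 (−0.15 to 0.26, percentile 72.4) over 24 genes. Cpt1b, the muscle carnitine palmitoyltransferase, was highest at 1.10, and Decr1 was lowest at −0.60.

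Immediate early genes were lower in the anti-miR library. These genes follow handling of cells, and with 1 library per group a difference in handling cannot be told apart from the knockdown. Of 15 above the floor, 13 were lower, 6 of them by at least 1.5-fold, and the median was −0.39 (−0.78 to −0.05), at percentile 0 of the random lists. Nr4a1 (chromosome 7, 140012800 to 140020589), an orphan nuclear receptor, had 92.1 and 42.3 RPM, a ratio of 0.459 (0.417 to 0.504), below its like-level range of −0.47 to 0.51 on the log2 scale. Dusp1, a MAP kinase phosphatase, had 514 and 285 RPM at −0.85, below its range of −0.39 to 0.30, and Fos stood at −0.35. Myc, also on the let-7 list, was the 1 member at least 1.5-fold higher, at 0.73.

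NF-kB targets and cytokines had a median of −0.35 (−0.93 to 0.10) at percentile 0.12, with 6 of 16 at least 1.5-fold lower and 1 higher. Lcn2, lipocalin 2, had 31 and 3 reads, a ratio of 0.105 (0.0205 to 0.336) and a log2 ratio of −2.75, inside its like-level range of −4.51 to 5.06, while Tnf was higher at 1.65. The chemokine gene Ccl2, among the most abundant members, stood at 0.32. Il1b, at −1.35, and Cxcl1, at −1.08, were chosen after their values were seen. With a floor of 10 RPM the list's median was −0.08 at percentile 14.2, inside the range of random lists. Interferon-stimulated genes had a median of 0.01 (−0.59 to 0.25, percentile 41.1) and a mean of −0.19, opposite in sign, with 7 of 23 at least 1.5-fold lower and 1 higher. Ifit3 was lowest at −1.81 and Usp18 highest at 1.62, both inside their like-level ranges of −2.69 to 5.28 and −3.69 to 5.23.

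Lysosome and autophagy genes were slightly lower. The median of 18 genes was −0.15 (−0.21 to −0.06) at percentile 0.13, and 14 were lower, 0 of them by 1.5-fold, with 1 at least 1.5-fold higher. The cathepsin genes Ctsd and Ctsb, with 11892 and 8101 RPM in the control, had log2 ratios of −0.21 and −0.28, Sqstm1 was lowest at −0.29 and Tfeb highest at 0.67. Unfolded protein response genes had a median of −0.03 (−0.12 to 0.09, percentile 22.8) over 19 genes, with Atf3 at −0.78 and the chaperone gene Hspa5 at 1708 and 1650 RPM. YAP target genes had a median of −0.09 (−0.21 to 0.09, percentile 7.69) over 15 genes, with Ctgf at −0.14 and Crim1 lowest at −0.69. In all, 8 of the 27 lists tested lay outside the central 95% of random lists, 5 above and 3 below. By chance alone 1.35 would, if lists and the genes within each were independent. Genes of a list that vary together would raise that number.

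**Figure D2:**
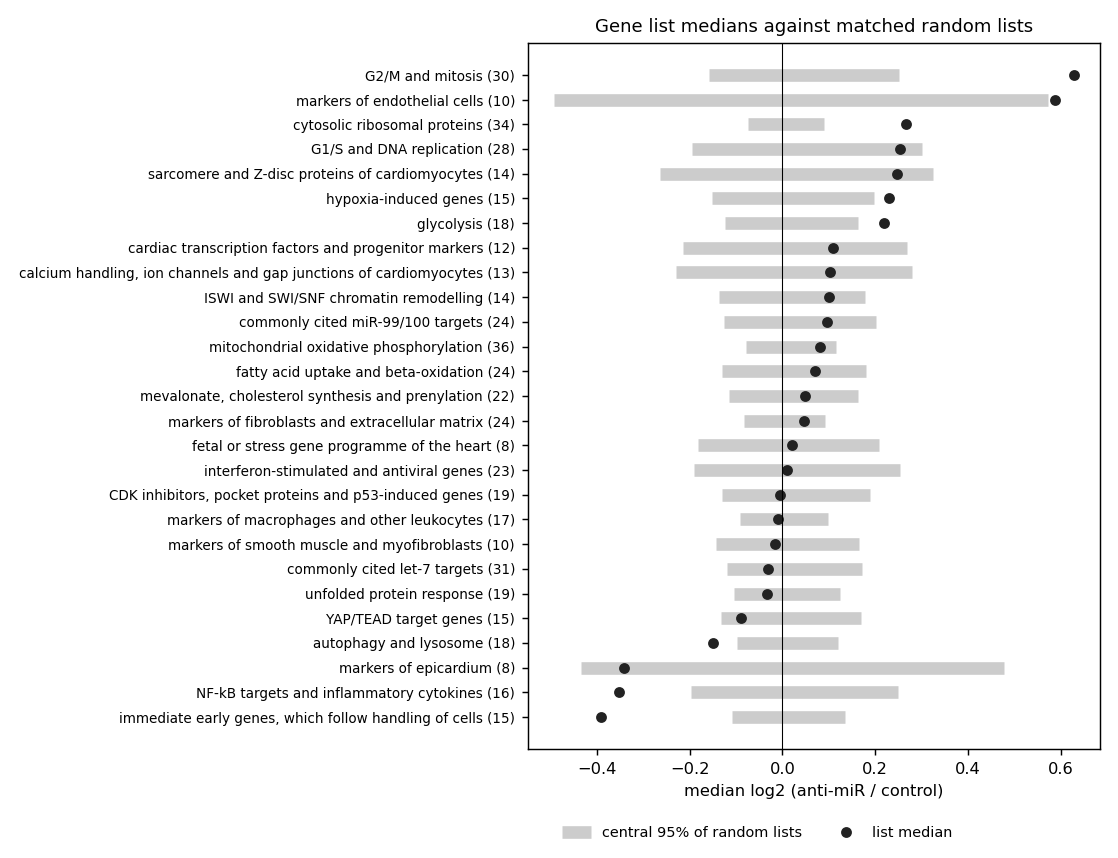
Median log2 ratio of anti-miR to control for each of the 27 gene lists (black points, with the number of members in brackets) beside the central 95% of 10000 matched random lists (grey bars). The G2/M list at 0.63 and the ribosomal proteins at 0.27 lie to the right of their bars, and the immediate early genes at −0.39 to the left.

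Across single genes, 503 of 10365 above the floor were at least 2-fold higher in the anti-miR library, 369 were at least 2-fold lower and 91.6% lay within 2-fold. Mdm1 (chromosome 7, 57455566 to 57482092), a centriole protein, had the highest ratio among genes of at least 5 RPM, with 11 and 150 reads, 14.8-fold higher (8.01 to 30.2). It was followed by Gatsl2, Mks1, Trmt11, Tfb1m, Osbpl6, Igfbp2, Dlgap5, Upp1, Aptx and Igfbp6, with log2 ratios from 2.55 down to 1.93. Mks1 acts in ciliogenesis, Dlgap5 in the mitotic spindle, and Igfbp2 and Igfbp6 bind insulin-like growth factors. Mmp9 (chromosome 3, 155985473 to 155993433), gelatinase B, had the lowest ratio among genes of at least 5 RPM, with 165 and 9 reads, 16.9-fold lower, at a ratio of 0.0590 (0.0265 to 0.115). Nr4a2, an immediate early relative of Nr4a1, had 621 and 126 reads, a log2 ratio of −2.17. Polr3b, Ccl9, Hexim2, Alkbh2, Lrfn1, Ccl6, Dnajc24, MGC108823, Epha3 and Scara3 followed, from −2.08 to −1.79, with the chemokine genes Ccl9 at −1.90 and Ccl6 at −1.85.

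The squared difference between the libraries was 12.5 to 19.4 times that of independent reads for genes of 50 to 5000 reads, a spread that counting error alone does not cover. A simulation with no changed gene used 14 reads per molecule, its scatter set from these libraries and so not independent of them. Its dispersion index was 15.8, above the observed median of 15.2. It gave 478 genes at least 2-fold higher and 512 lower of 10345, against the 503 and 369 of 10365 observed. Among genes of at least 5 RPM it gave 355 genes at least 2-fold apart, against 171 higher and 112 lower observed.

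**Figure D3:**
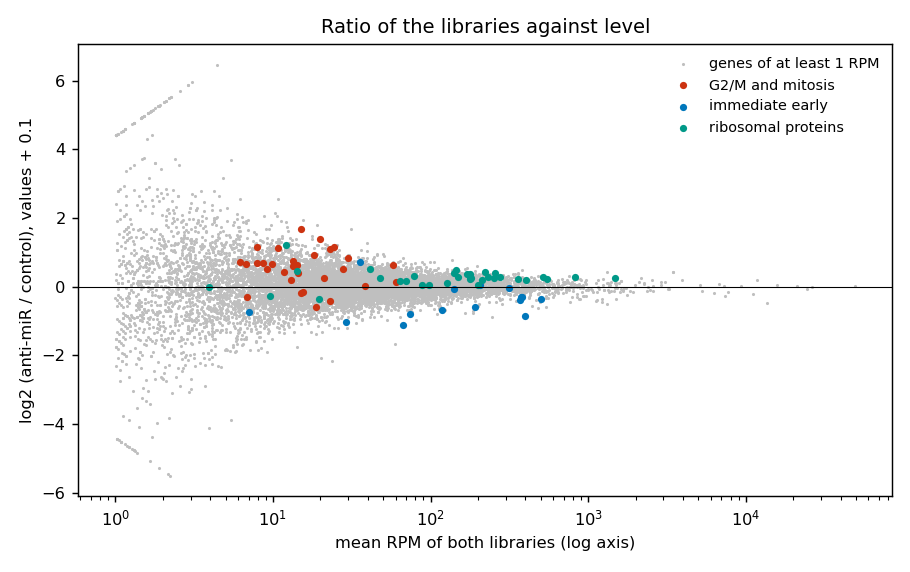
Log2 ratio of anti-miR to control against mean level in RPM (log axis) for the 10365 genes above the floor (grey), with genes of G2/M and mitosis, immediate early genes and ribosomal protein genes in colour. The spread narrows with level; the highest red point is Racgap1 at 1.67 and the lowest blue point Nr4a1 at −1.12.

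**Figure D4:**
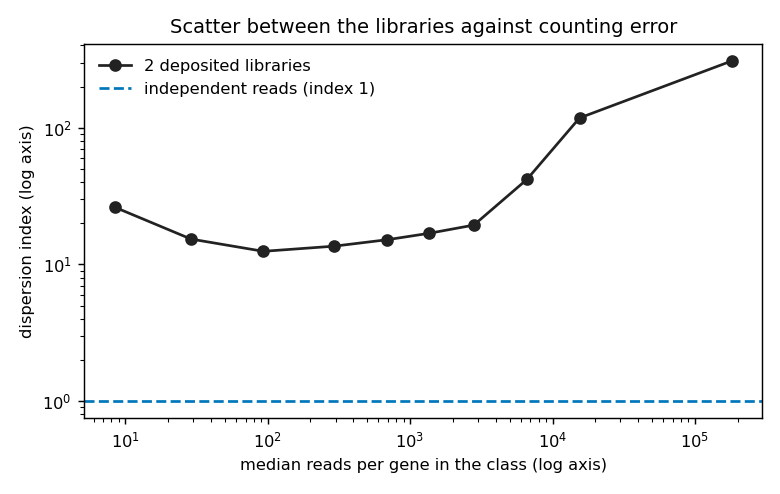
Dispersion index, the squared difference between the 2 libraries relative to that of independent reads, against the median reads per gene in 10 classes of genes, both on log axes, with independent reads at 1 (dashed). The index lies between 12.5 and 19.4 from 50 to 5000 reads and reaches 308 in the highest class.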

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

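The exact binomial test on reads and the floor of 5 RPM were chosen after the result was seen; the other alternatives were not. More genes were higher than lower in the anti-miR library under each alternative run, from 503 and 369 under the main rule. With a pseudocount of 1 RPM 350 genes were higher and 238 lower. Without a floor 1189 were higher and 710 lower, with a floor of 10 RPM 84 and 37, and with a floor of 5 RPM 171 and 112; a higher floor leaves fewer low genes in the count. A ratio of 1.5 gave 1124 and 887 genes and a ratio of 3 gave 230 and 153. The exact binomial test called 3282 and 2736 genes, 58.1% of those above the floor, and counts reads as independent. Of 187 list medians recomputed over 27 lists and 7 settings, 187 stayed within the list's interval over members. Of these, 6 changed sign, in 3 lists near 0 that were not apart from random lists: the fetal and stress genes (0.02, and −0.07 with a floor of 10 RPM and −0.01 with either other scaling), the interferon genes (0.01, and −0.02 with either other scaling) and the smooth muscle markers (−0.02, and 0.01 without a floor). With a floor of 10 RPM the NF-kB list (−0.08, percentile 14.2) and the hypoxia list (0.17, percentile 95.8) moved inside the range of random lists, and the endothelial list had too few members for a value. The other 5 lists called apart stayed outside it in the 7 settings. Only the pseudocounts and floors could move a percentile. Both other scalings shifted every log2 ratio by −0.03, which leaves percentiles as they were. Summing rows moved nothing, since the 1 repeated symbol is at 0. Depth limits the lowest genes: 3 reads, the limit that a count of 0 allows, correspond to 0.187 and 0.203 RPM. The seed-site analysis was not run. No paired analysis was possible because each group has 1 library.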

Other observations

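The scan of gene families, the counts of genes seen in a single library, the dispersion index and the tests of explanations were chosen only after the result was seen; the medians and random lists of the gene lists were fixed beforehand. A scan covered 116 families of genes that share a symbol stem, each set against 2000 random lists matched on level. The stems Rpl and Rps were higher in the anti-miR library. The 37 Rpl genes had a median log2 ratio of 0.27 at percentile 100, with 29 higher, and the 30 Rps genes 0.21 at percentile 99.95, with 24 higher. The stems Cdk (21 genes, 0.24, percentile 99.1) and Kif (24 genes, 0.23, percentile 97.65) were also high, as was Ptpn (13 genes, 0.24, percentile 98.55, 11 higher), while Gpr was low (31 genes, −0.23, percentile 1.3, 20 lower). Rpl shares genes with the ribosomal protein list, so it adds no separate evidence. Cdk shares only Cdk1 with the G2/M list, and Kif shares Kif11, Kif20a, Kif23 and Kif2c. Most genes of these 2 stems are thus not on that list, and medians without the shared genes were not computed. A stem groups genes by symbol alone, so its members need not be of the same kind. Protocadherin alpha genes (Pcdha) were lower in 13 of 13, with a median of −0.36 at percentile 0.25; these transcripts share their last exons, so the 13 values are not independent. In all 7 of the 116 families lay outside the central 95% of random lists, 5 above and 2 below. By chance 5.8 would, if families and the genes within each were independent.

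Genes seen in a single library were more numerous in the anti-miR library. With over 20 reads there and 0 in the control there were 110 genes, against 65 the other way. Zfp90, a zinc finger gene, had 0 and 130 reads, and was chosen after its values were seen. The anti-miR library had 454 genes with 1 to 5 reads and the control 176, while genes with 21 to 25 reads numbered 164 and 158.

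The list of 30 mitotic genes had a higher median in the anti-miR library than 10000 random lists. A larger share of fibroblasts or leukocytes would raise their markers too. The intervals of both marker medians end at or below 0.16, under the lower end of 0.39 for the mitotic list. Single leukocyte markers went both ways beyond their like-level ranges, Lyz2 at 0.42 (−0.39 to 0.30) and C1qa at −0.57 (−0.38 to 0.30). The medians therefore speak only for each marker list as a whole. For the 30 listed mitotic genes, 0 of 10000 matched random lists reached the median of 0.63 (0.39 to 0.73). That argues against independent scatter of single genes as the source for this list. The 47 further mitotic genes did not repeat the difference beyond such scatter. Their median of 0.19 (−0.07 to 0.56), with 30 of 47 higher, was reached by 912 of 10000 random lists. This test was set before the median of the 47 genes was computed. A larger share of endothelial cells cannot be told apart, since the endothelial median of 0.59 has an interval from −3.33 to 1.12. The knockdown and any other difference between the cultures cannot be told apart either with 1 library per group, so an effect of the inhibitors on cell division may be one reading among several.

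Most sarcomere transcripts were scarce in both libraries, with exceptions such as Tnnt2 at 147 and 161 RPM. The protocol removes attaching cells by pre-plating and states a purity above 90%. RNA of fibroblasts and macrophages in the cultures is a candidate explanation: 85.0% of leukocyte markers and every fibroblast marker lay at 5 RPM or above, led by Lyz2 at 2937 and Col1a1 at 49138 RPM in the control. Of the measured markers, 2 of 24 fibroblast genes (Col1a2 and Pdgfra) and 0 of 20 leukocyte genes stand on another list. Cardiomyocytes that lost their contractile transcripts, with no other cells present, would leave leukocyte markers near 0, and these had a median of at least 306 RPM in each library; such loss beside other cells stays open. Loss of reads in counting cannot be told apart either. Of 48 measured sarcomere and calcium genes 60.4% lay under 5 RPM, against 28.3% of the more abundant ribosomal protein genes, but Gapdh had only 45 and 34 reads and Rpl38 had 0. At 5 RPM or above were 30.4% of sarcomere genes and 48% of calcium and channel genes. Of all 16846 symbols 8959 lay there, so calcium and channel genes were near the share over all genes.

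The libraries differed far beyond counting error, and the dependence on level bears on the source. From 50 to 5000 reads the dispersion index had a log-log slope of 0.13 on reads, nearly flat. Reads that are copies of a small number of molecules would give such a slope. If every molecule were copied equally, the index of 15.2 could be read as copies per molecule, but few genes would then have 1 to 5 reads. In the control 176 genes and in the anti-miR library 454 genes had 1 to 5 reads. Equal copying at that number therefore does not cover the low counts, and the slope alone does not show how copies are spread over molecules. The index comes from the difference between the libraries, so it gives no number of molecules for either library. Differences of the same relative size at every level would give a slope near 1, and the slope of 0.13 argues against them as the whole source in that range. Below that range the index was 15.3 for genes of 15 to 50 reads and 26.2 for genes of 5 to 15 reads. Above 5000 reads the index climbed to 308, so other differences add to it there. Scatter from copied reads and real differences between the cultures cannot be told apart as the source of the 872 genes at least 2-fold apart, since each group has 1 library. A simulation with no changed gene gave 990, more than observed, but took its scatter from the same libraries. Its index of 15.8 also lay above the observed 15.2, so its excess over 872 decides nothing.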
